A study of Mus musculus with 13 samples.

How the data were processed

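RNA was measured in 13 heart samples of wild-type male C57BL/6Nj mice. Per the labels' protocols, total RNA was taken from the apex of the heart and made into libraries with the KAPA HyperPrep kit with RiboErase, which removes ribosomal RNA. Groups were read from the sample titles: 3 SHAM hearts with an empty AAV9 carrier, 3 SHAM hearts with AAV9 carrying Zeb2os, 3 I/R hearts with the empty carrier and 4 I/R hearts with Zeb2os. Nothing in the labels ties samples of different groups to each other. The labels do not state that every sample is a separate animal, so p-values of single genes measure the spread between these samples.

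The values used here are the authors' own comparison tables, so all steps up to the fold change are theirs. Per the submitters' processing notes, Trim Galore and DESeq2 were among the tools and GRCm38/mm10 was the genome build. The aligner, the counting program, the gene annotation, the tool versions and whether counting used the strand of a read are not given in the sources used here. Per the file headers, each deposited table lists for every gene a mean signal, which is the mean of size-factor normalized counts over the libraries compared. It also lists the authors' log2 fold change with its standard error. A Wald score, the fold change over its standard error, is listed per the file headers. The deposited tables end with a p-value and an adjusted p-value per gene. Other deposited tables list biological process terms and pathways with the number of genes in each term, a fold enrichment and a p-value, as the authors computed them. Values per library were not analysed here, so no SD across replicates, no count of replicates that share a direction and no depth per library can be given. The depth of each library is unknown for that reason.

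The tables were checked before use. The SHAM table listed 26214 genes, of which 21622 had a p-value and an adjusted p-value. The I/R table of 4 Zeb2os libraries against 3 controls had 20861 genes with a p-value and 12884 with an adjusted p-value, the latter being genes with a mean of at least 68.0 normalized counts. A further deposited table compared 4 libraries against 4. It holds an I/R library that is not among the 13 samples and is not analysed here otherwise, and the table was used as an alternative only. In the SHAM table the sign of the log2 column was opposite to that of the Wald column for 20690 genes. Fold changes were oriented throughout as Zeb2os minus empty, with the delivered Zeb2os gene as the guide to direction. The titin gene Ttn took 8.66% of the summed mean normalized counts in SHAM and 7.92% in I/R, and the ribosomal RNA precursor Rn45s took 4.26% and 5.07%.

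A gene was called at the authors' adjusted p-value under 0.05. Intervals are 95% normal intervals from the deposited standard error. The planned count models, with their leave-out fits and permutations, need values per library. The tests below replaced them and were chosen after the form of the tables was known. Gene lists were tested with limma's cameraPR on the Wald score, with a preset correlation between genes of 0.01, over genes with a mean of at least 10 normalized counts. A p-value of this test sets the genes of a list against the other genes. It does not measure the spread of the list between samples. Of 35 lists fixed before the data were examined, 32 had at least 5 measured members in every comparison, and Benjamini-Hochberg adjustment ran over those 32. For every list the number of members past 0.05 after adjustment over the list alone was also counted. A preset correlation cannot be replaced by an estimated one without values per library, so 0.05 was tried beside 0.01. The difference between the Zeb2os effect in I/R and in SHAM was tested per gene as the difference of the log2 fold changes over the root of their summed squared standard errors, with Benjamini-Hochberg adjustment. Correlations of fold changes were taken across genes, which are not independent replicates, and no p was computed for them. The 2 comparisons share no library. Tables were normalized separately, so no level was compared between them and I/R hearts were not set against SHAM hearts.

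Gene positions, transcript GC content and the overlap of Zeb2os with Zeb2 came from GENCODE M21 on GRCm38, and 95.1% of the gene names in the tables matched it. As an alternative, the trend of the log2 fold change over the GC content of the longest transcript was removed with a natural cubic spline with 5 knots, weighted by the inverse squared standard error. Standard errors were left as deposited. Other alternatives were an adjusted p threshold of 0.10, adjustment over genes above other mean counts, rank-based list tests and the other deposited I/R tables.

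Most genes named in the text followed a rule written before the data were examined. The rule took Zeb2os and Zeb2, the 8 largest and 8 smallest fold changes past the threshold with a mean of at least 50 normalized counts, and up to 2 members per list by smallest p. Where fewer than 5 genes passed, the 10 genes with the smallest p at a mean of at least 50 were added, leaving out predicted genes and clone symbols. A criterion on groups that do not overlap needed values per library and was dropped. Further genes were named after their values had been seen. These were Rgs5, Myh11, Myl4, Dkk3, Myh7, Nppa, Col3a1, Gsn, Dcn, Lum, Postn, Fap and Lrrc15, the calls left after GC adjustment, and genes of the added families or without a p.

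Each step was tested on simulated data with 100 genes shifted by a log2 fold change of 1 and 100 shifted by 2. At those sizes 64% and 93% were recovered in SHAM over 15223 genes, 76% and 87% in I/R over 15203 genes, and 39% and 80% in the difference over 15058 genes. A GC trend added to the I/R simulation gave 303 unchanged genes called before its removal and 10 after. In each comparison 3 of 3 lists shifted by 0.5 were called and 0 of 29 others. The simulated genes were independent of each other, so these counts do not show how often lists of correlated genes are called falsely. Simulated noise followed the deposited standard errors, and adjustment ran over the simulated genes in place of the authors' own. In the data the SD of the Wald scores across genes was 0.79 in SHAM and 1.62 in I/R. Recovery and false calls may therefore differ for the calls reported. Most list medians in SHAM were smaller than 0.5, and recovery of lists at smaller shifts was not tested. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used. All tests were two-sided.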

Results

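The series measured heart RNA in mice after SHAM or I/R surgery (I/R is the usual cardiac abbreviation for ischemia and reperfusion). The mice had received an AAV9 carrier in the heart, either empty or carrying Zeb2os, a long noncoding RNA transcribed antisense to Zeb2. AAV9 is an adeno-associated virus used to bring genes into heart muscle. There were 3 samples per group, except for 4 in the I/R group with Zeb2os. The design asks what added Zeb2os changes in the heart without and with injury, and the series title points to Zeb2 and to cardiomyocyte dedifferentiation. Gene values are the authors' log2 fold changes with their standard errors (SE), as Zeb2os minus empty.

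Zeb2os itself was far above the controls in both surgeries. The gene lies on chromosome 2 at 45110707 to 45114087 on the + strand (ENSMUSG00000052248.16, annotated as antisense, GRCm38), inside the span of Zeb2 at 44983632 to 45117395 on the − strand (ENSMUSG00000026872.17, protein coding). In the authors' deposited table for SHAM hearts Zeb2os rose by 7.53 (SE 0.79, adjusted p = 3.3e-17) at a mean of 11422 normalized counts. For I/R hearts the authors' deposited table gives a rise of 9.22 (SE 0.35, adjusted p = 3.76e-152) at a mean of 20723. The 95% intervals were 5.98 to 9.08 and 8.54 to 9.89. Zeb2, a zinc finger transcription factor, did not pass the threshold in either surgery, and the authors' deposited tables give −0.01 (SE 0.13, adjusted p = 1) in SHAM and −0.02 (SE 0.14, adjusted p = 0.948) in I/R. Its intervals ran from −0.27 to 0.24 and from −0.29 to 0.26. Of the 1990 exonic bases of Zeb2os, 653 (32.8%) are also exonic in Zeb2, so reads there cannot be assigned if counting ignored strand, which makes both values uncertain.

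In SHAM hearts, genes of heart muscle metabolism stood slightly higher with Zeb2os and genes of matrix, activated fibroblasts, vessels and cell division slightly lower, while Zeb2os was the only gene past the threshold. Fatty acid oxidation genes had a median log2 fold change of 0.27, with 23 of 25 members above 0 (cameraPR adjusted p = 5.57e-09). Oxidative phosphorylation genes had a median of 0.18 with 34 of 35 above 0 (adjusted p = 1.4e-06), and citrate cycle genes 0.19 with 16 of 16 above 0 (adjusted p = 3.15e-05). The cell cycle list had a median of −0.49 with 25 of 29 members below 0 (adjusted p = 1.87e-07). Extracellular matrix genes had a median of −0.34, with 27 of 27 below 0 (adjusted p = 3.83e-05).

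Of the 32 testable lists, 14 passed in SHAM, 6 higher and 8 lower. The other higher lists were adult sarcomere genes (median 0.16, 20 of 20 above 0, adjusted p = 1.56e-04), calcium handling and excitation genes (0.16, adjusted p = 0.00168) and glycolysis genes (0.10, adjusted p = 0.0341). Myofibroblast markers had the lowest median, −0.68, with 18 of 19 below 0 (adjusted p = 2.61e-05). Endothelial markers (−0.22, adjusted p = 3.81e-04), angiogenesis genes (−0.22, adjusted p = 0.00793), interferon-stimulated genes (−0.20, 23 of 24 below 0, adjusted p = 3.07e-04), lymphocyte markers (−0.47, adjusted p = 0.0115) and dedifferentiation markers (−0.24, 14 of 18 below 0, adjusted p = 0.0483) were lower. Adjusted over the list alone, 1 lymphocyte member fell and no member of the other 13 lists passed. With a preset correlation of 0.05 the tests gave adjusted p = 0.152 for dedifferentiation, 0.134 for glycolysis and 0.0623 for angiogenesis, which ended those 3 calls.

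List members with the smallest p in the authors' deposited table for SHAM were Pdk4, a kinase that holds back glucose oxidation, at 0.77 (SE 0.43) and Mlycd, malonyl-CoA decarboxylase, at 0.40 (SE 0.24). For the sarcomere the authors' deposited table gives 0.21 (SE 0.17) for Myom1 and 0.24 (SE 0.21) for Myoz2, and for calcium handling 0.29 (SE 0.25) for the pump gene Atp2a2. Among matrix and scar genes the authors' deposited table lists Cthrc1 at −2.16 (SE 0.91), Fmod, which encodes the collagen-binding fibromodulin, at −1.79 (SE 1.09) and Tnc (tenascin C) at −1.02 (SE 0.68). The mitotic kinase gene Cdk1 stood at −1.19 (SE 0.52), the T cell kinase gene Lck at −1.96 (SE 0.59), the natural killer cell receptor gene Klrb1c on the other side at 1.38 (SE 0.66) and the endothelial factor gene Sox18 at −0.49 (SE 0.33) in the authors' deposited table. None of these passed, and each had an adjusted p of 1. Among genes with a mean of at least 50 normalized counts, leaving out predicted genes and clone symbols, the smallest p after Zeb2os belonged to Snhg20, a noncoding RNA gene. It stood at −1.004 (SE 0.25, adjusted p = 0.627) in the authors' deposited table, followed by H2bc14 at −1.42 (SE 0.42) and Ptpn22 at −0.96 (SE 0.29). At an unadjusted p under 0.05 the authors' deposited table has 254 genes, 54 higher and 200 lower, which is fewer than the 1081 that chance alone would give among 21622 genes. That chance number assumes Wald scores with an SD of 1 where nothing changed. The SD here was 0.79 over genes with a mean of at least 10, so the low count does not show that no gene changed.

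**Figure D1:**
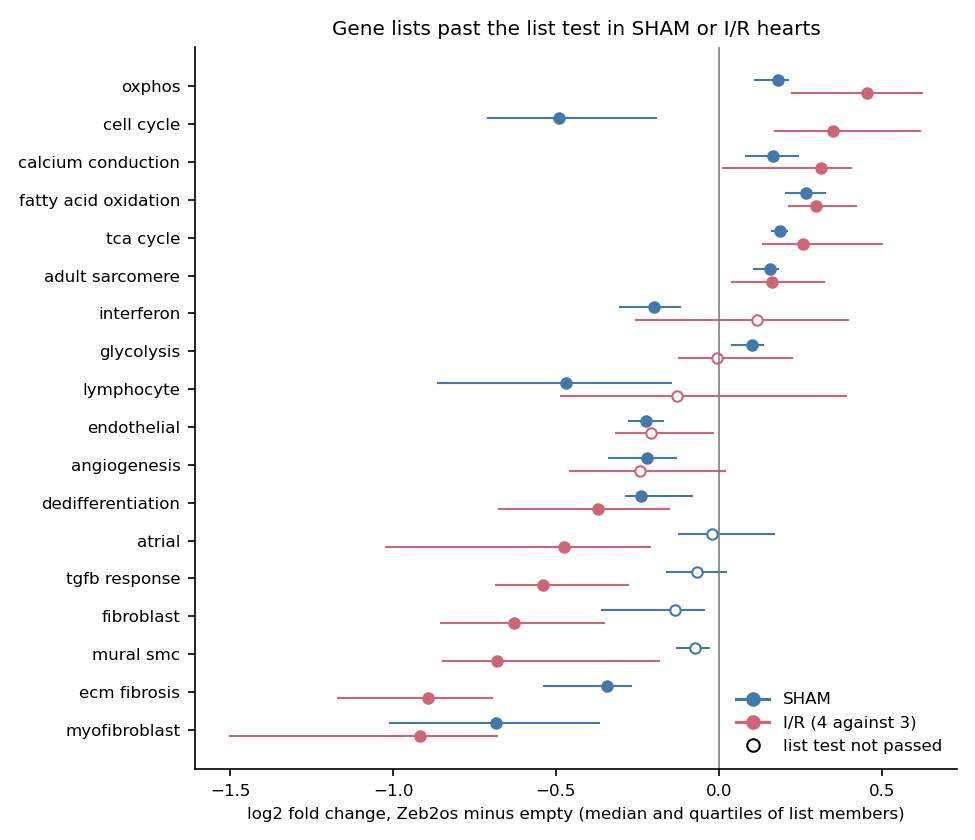
Median log2 fold change (points) with lower and upper quartiles (lines) of the members of each list that passed the list test in SHAM or I/R hearts, Zeb2os minus empty on the x axis, with open points for lists that did not pass in that surgery. Extracellular matrix genes lie at −0.34 in SHAM and −0.89 in I/R, and cell cycle genes lie on opposite sides of 0, at −0.49 and 0.35.

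In I/R hearts, Zeb2os went with higher expression of respiratory chain and other heart muscle genes and lower expression of matrix, fibroblast and smooth muscle genes. The authors' deposited table of 4 against 3 libraries has 602 genes past the threshold, 380 higher and 222 lower. Oxidative phosphorylation genes had a median of 0.46 with 35 of 35 above 0 (cameraPR adjusted p = 1.02e-10), and 6 of them rose, or 21 when adjusted over the list alone (0 with 4 against 4 libraries). Extracellular matrix genes had a median of −0.89 with 27 of 27 below 0 (adjusted p = 3.15e-06), of which 1 fell, or 10 when adjusted over the list alone (0 with 4 against 4). Smooth muscle and pericyte markers had a median of −0.68 (adjusted p = 9.18e-05), and 6 of 15 fell, or 9 when adjusted over the list alone (1 with 4 against 4).

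The cytochrome c oxidase subunit genes Cox7b and Cox6c rose by 1.21 (SE 0.32, adjusted p = 0.0378) and 1.18 (SE 0.32, adjusted p = 0.0378) in the authors' deposited table for I/R. The citrate cycle list (median 0.26, 15 of 16 above 0, adjusted p = 8.15e-04) had 2 members that rose, or 4 when adjusted over the list alone (0 with 4 against 4). These were Sucla2 at 0.83 (SE 0.26) and Dld at 0.79 (SE 0.26) in the authors' deposited table. Fatty acid oxidation genes had a median of 0.30 (21 of 25 above 0, adjusted p = 0.00228), and the fatty acid transporter gene Cd36 rose by 0.84 (SE 0.26) in the authors' deposited table. Calcium handling genes had a median of 0.31 (adjusted p = 0.0217) with Trdn (triadin) up by 1.08 (SE 0.30) and Casq2 (calsequestrin) up by 0.95 (SE 0.28) in the authors' deposited table. In that list 4 rose and 1 fell when adjusted over the list alone, and 0 did either with 4 against 4. The sarcomere list (median 0.16, adjusted p = 0.0331) had 1 member past the threshold, Nebl at 0.68 (SE 0.21) in the authors' deposited table. With a preset correlation of 0.05 the calcium and sarcomere lists gave adjusted p = 0.103 and 0.132.

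Fibroblast markers had a median of −0.63 with 15 of 16 below 0 (adjusted p = 1.73e-04), and 2 fell, or 5 when adjusted over the list alone (0 with 4 against 4). In the authors' deposited table for I/R, Gfpt2 fell by 1.18 (SE 0.30, adjusted p = 0.0352) and the secreted protease gene Htra3 fell by 0.84 (SE 0.25, adjusted p = 0.0433). Myofibroblast markers had a median of −0.92 with 17 of 19 below 0 (adjusted p = 8.15e-04), and 3 fell. These were the cartilage matrix gene Chad at −2.01 (SE 0.58), Cilp2 and the smooth muscle actin gene Acta2 in the authors' deposited table. The abundant member Postn stood at −0.06 (SE 0.40, mean 28553 normalized counts) there. The 2 members above 0 were Fap at 0.42 (SE 0.27) and Lrrc15 at 0.23 (SE 0.31). Of the TGF-beta list (median −0.54, 15 of 17 below 0, adjusted p = 0.00228), Tgfb3 fell by 1.20 (SE 0.39), and the matrix cross-linking enzyme gene Loxl1 of the matrix list fell by 1.17 (SE 0.37), in the authors' deposited table. Among smooth muscle genes the authors' deposited table has falls of Lmod1 (leiomodin 1) by 1.48 (SE 0.31, adjusted p = 0.00681), Myh11 (smooth muscle myosin) by 1.19 (SE 0.30) and Mylk (myosin light chain kinase) by 0.80 (SE 0.20). The pericyte marker Rgs5 stood on the other side, at 0.72 (SE 0.24, adjusted p = 0.054) in the authors' deposited table. It was the 1 member of the list to rise when adjusted over the list alone, which it did not with 4 against 4. Atrial markers were lower beside these matrix, fibroblast and smooth muscle genes, with a median of −0.47, and the atrial genes Myl4 and Dkk3 stood at −2.60 (SE 1.67) and −1.59 (SE 0.77) in the authors' deposited table without passing.

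Dedifferentiation markers had a median of −0.37 with 17 of 18 below 0 (adjusted p = 0.00101), and 6 fell when adjusted over the list alone (0 with 4 against 4). Of the 18 members 7 are in other lists as well. The member past the threshold over all genes was the smooth muscle actin gene Acta2, which fell by 0.68 (SE 0.21) in the authors' deposited table and belongs to the mural and myofibroblast lists as well. The fetal myosin gene Myh7 and the natriuretic peptide gene Nppa stood at −0.34 (SE 0.71) and −0.09 (SE 0.60) in the authors' deposited table. The cell cycle list was higher (median 0.35, 25 of 29 above 0, adjusted p = 0.0134) with no member past the threshold, and Kif11 stood at 0.85 (SE 0.36) and Ccne1 at 0.94 (SE 0.41) in the authors' deposited table. Atrial markers, included because a dissection can differ in how much atrium it holds, had a median of −0.47 with 8 of 9 below 0 (adjusted p = 0.0217). The list test here also held Sln and Myl7, which have a fold change but no p-value. Stard10 stood at −1.02 (SE 0.41) and Kcna5 at −0.50 (SE 0.23) in the authors' deposited table. With a preset correlation of 0.05 the cell cycle and atrial lists gave adjusted p = 0.103 and 0.0702. With 4 against 4 libraries the cell cycle list had a median of 0.21 and did not pass (adjusted p = 0.0717).

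Among genes past the threshold with a mean of at least 50 normalized counts, leaving out predicted genes with Gm symbols, the largest rises after Zeb2os in the authors' deposited table were Tmem267 at 1.66 (SE 0.46), the zinc finger genes Zfp979 at 1.48 (SE 0.33), Zfp97 at 1.38 (SE 0.37), Zfp960 at 1.37 (SE 0.38) and Zfp947 at 1.34 (SE 0.36), the cohesin acetyltransferase gene Esco2 at 1.44 (SE 0.45) and the kinetochore gene Knl1 at 1.32 (SE 0.33). The lowest of such genes was Col2a1, the cartilage collagen gene, which fell by 5.19 (SE 1.44) at a mean of 80.0 normalized counts in the authors' deposited table. Cilp2 at −2.42 (SE 0.79), Chad, B4galnt3 at −1.80 (SE 0.49), Plekha7 at −1.74 (SE 0.48), the heat shock gene Hspa1a at −1.58 (SE 0.46) and the kinase gene Brsk1 at −1.49 (SE 0.35) followed in the authors' deposited table. Single members of other lists that passed were the monocyte receptor gene Ccr2 at 1.17 (SE 0.31), the interferon-inducible GTPase gene Iigp1 at 0.82 (SE 0.22), the mitophagy gene Bnip3 at 0.81 (SE 0.25), the clock gene Npas2 at −1.23 (SE 0.38), the endothelial receptor gene Eng at −0.56 (SE 0.18) and Notch1 at −0.72 (SE 0.23), all in the authors' deposited table.

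**Figure D2:**
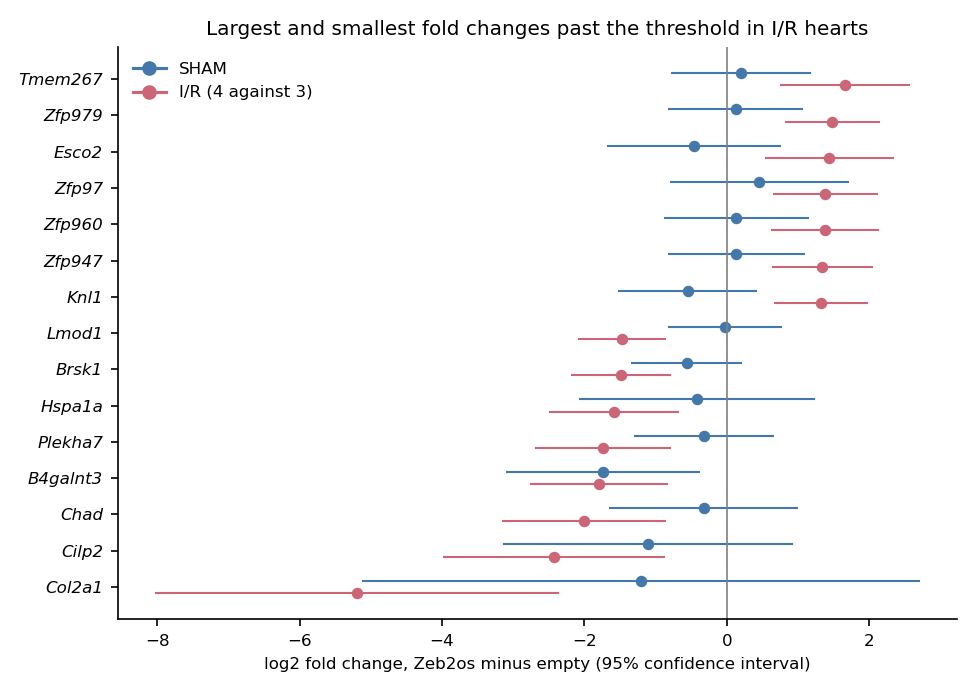
Log2 fold change, Zeb2os minus empty (points), with 95% intervals (lines) in SHAM and I/R hearts for the genes with the largest and smallest fold changes past the threshold in I/R at a mean of at least 50 normalized counts, without Zeb2os and predicted Gm genes. Col2a1 lies lowest at −5.19 in I/R and Tmem267 highest at 1.66.

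The lists that did not pass in either surgery were fetal and stress genes (median 0.12 in SHAM and 0.04 in I/R), macrophage (−0.06 and −0.22), neutrophil (0.05 and 0.24), cytokine (−0.08 and 0.22), antigen presentation (−0.13 and −0.22), hypoxia (0.04 and −0.13), stress response (0.05 and −0.27), epithelial and mesenchymal ZEB target (−0.13 and −0.42), immediate early (0.03 and −0.23), circadian (0.08 and 0.00), epicardial (−0.25 and −0.25), adipocyte (0.08 and −0.20), Schwann cell (−0.22 and −0.10) and skeletal muscle (0.08 and −0.17) genes. In I/R the endothelial (−0.21, adjusted p = 0.0791), angiogenesis (−0.24, adjusted p = 0.0649), lymphocyte (−0.13, adjusted p = 0.872), interferon (0.12, adjusted p = 0.292) and glycolysis (−0.01, adjusted p = 0.431) lists did not pass, nor did the fibroblast (adjusted p = 0.0888), mural (0.406), TGF-beta (0.72) and atrial (0.941) lists in SHAM. Some of these lists passed under another setting. In I/R the ZEB target list (adjusted p = 0.0582) passed by ranks (0.041), after GC adjustment (0.0357) and with 4 against 4 (0.0179). Macrophage markers passed in I/R with 4 against 4 (0.0179), glycolysis (0.00264) and angiogenesis genes (0.0167) in I/R after GC adjustment, and fibroblast markers in SHAM by ranks (0.0464). With 4 against 4 the I/R medians of several lists that did not pass moved by over 1.5 times, to −0.10 for endothelial, −0.09 for angiogenesis, 0.11 for neutrophil, 0.12 for cytokine, −0.07 for hypoxia, −0.10 for immediate early, −0.23 for Schwann cell, 0.02 for skeletal muscle, 0.09 for glycolysis, −0.05 for circadian and 0.00 for fetal and stress genes. Median and test differed in sign for glycolysis and circadian genes in I/R and for stress response genes in SHAM. Red blood cell markers had 4 measured members, the locus list 2 and the mitochondrially encoded list 0, and none of these lists was tested.

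Fold changes in I/R followed the GC content of the transcript. Across genes the Spearman correlation of log2 fold change with GC content was −0.55 in I/R and −0.08 in SHAM, and the medians in I/R ran from 0.67 under 38% GC to −0.35 at 58% and above. Genes called higher had a median GC content of 40.1%, genes called lower 56.6%, and genes not called 49.7%. Removing the fitted trend left Spearman correlations of −0.13 in I/R and −0.16 with 4 against 4 libraries, so the removal was not complete. With the fitted trend removed, 9 genes passed in I/R, 2 higher and 7 lower. Of the 583 calls with a GC value 6 remained, namely Zeb2os, Lmod1, Traf5, Kcna6, Peg3 and Rab20. Zeb2 then stood at −0.37 (adjusted p = 0.189), computed from the authors' deposited table. The calcium list ended at adjusted p = 0.0855, while the matrix (median −0.78), fibroblast (−0.57), myofibroblast (−0.95), mural (−0.47), oxidative phosphorylation (0.45) and cell cycle (0.33) lists still passed. The authors' deposited table of 4 against 4 libraries has 1 gene past the threshold, Zeb2os, with 1014 genes at an unadjusted p under 0.05, 178 higher and 836 lower (1049 by chance), against 4066 in the table of 4 against 3, 2137 higher and 1929 lower (1043 by chance). The single-gene calls named above other than Zeb2os ended there, and in that authors' deposited table several rises were over 1.5 times smaller, with Cox7b at 0.65, Cox6c at 0.61, Sucla2 at 0.54, Cd36 at 0.43, Trdn at 0.60, Casq2 at 0.48, Nebl at 0.42, Zfp979 at 0.93, Zfp97 at 0.57, Zfp960 at 0.63, Zfp947 at 0.79, Esco2 at 0.73, Knl1 at 0.65, Ccr2 at 0.51, Iigp1 at 0.43 and Bnip3 at 0.38. Of the genes named without passing, Kif11 stood at 0.37, Ccne1 at 0.52, Rgs5 at 0.48 and Kcna5 at −0.31 in that authors' deposited table.

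**Figure D3:**
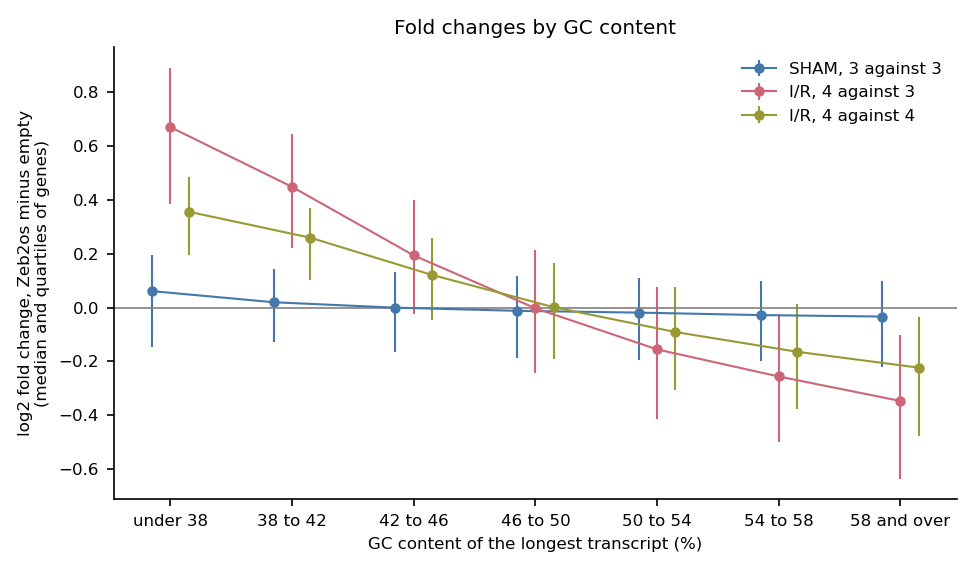
Median log2 fold change, Zeb2os minus empty (points), with lower and upper quartiles of the genes (bars), by GC content of the longest transcript in percent, for SHAM, I/R with 4 against 3 libraries and I/R with 4 against 4. The I/R medians of 4 against 3 fall from 0.67 to −0.35, those of 4 against 4 from 0.36 to −0.22 and those of SHAM from 0.06 to −0.03.

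In the difference of the Zeb2os effect between I/R and SHAM, groups of genes stood apart from the other genes by the list test, while no gene alone passed. The list test does not measure the spread between samples. It therefore does not show that the effect differed beyond the variation between hearts. In the simulation this test per gene recovered 39% of genes shifted by 1, so differences of single genes may have been missed. Cell cycle genes had a median difference (I/R minus SHAM) of 0.80 with 28 of 29 above 0 (cameraPR adjusted p = 4.93e-09), oxidative phosphorylation genes 0.28 (adjusted p = 0.00102) and interferon-stimulated genes 0.24 (adjusted p = 0.00261). Matrix (−0.53, adjusted p = 0.00375), fibroblast (−0.44, adjusted p = 0.00368), TGF-beta (−0.44, adjusted p = 0.00375), mural (−0.49, adjusted p = 0.00368) and atrial genes (−0.53, adjusted p = 0.0226) differed the other way. With a preset correlation of 0.05 the matrix and atrial lists both gave adjusted p = 0.055. With the I/R table of 4 against 4 the oxidative phosphorylation list still passed, at adjusted p = 0.0116, and its I/R median was 0.33 in place of 0.46. The remaining 24 lists did not pass.

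Per gene, 0 of 15521 genes passed the test of the difference, with 523 at an unadjusted p under 0.05, against 776 by chance. That number was 153 of 15487 genes with the I/R table of 4 against 4 (774 by chance) and 304 of 15059 after GC adjustment (753 by chance), and 0 genes passed in either. From the values of the authors' deposited tables the difference was 1.68 (SE 0.86, adjusted p = 0.844) for Zeb2os, with an interval of −0.01 to 3.37, and −0.00 (SE 0.19, interval −0.38 to 0.37) for Zeb2. Among genes with a mean of at least 50 normalized counts in both surgeries, leaving out predicted genes and clone symbols, the smallest p belonged to the centromere gene Cenpi. Its difference was 2.39 (SE 0.73) from the authors' deposited tables. It was followed by Ric3 at 1.01 (SE 0.31), Knl1 at 1.87 (SE 0.59), Snhg20 at 1.06 (SE 0.34), the helicase gene Blm at 1.02 (SE 0.34) and Nlrp5-ps at −1.04 (SE 0.35), from the authors' deposited tables. Next came the checkpoint kinase gene Chek1 at 1.54 (SE 0.52), the kinetochore gene Nuf2 at 2.07 (SE 0.70), Cntfr at −1.38 (SE 0.47) and Zfp703 at −0.88 (SE 0.30), from the authors' deposited tables. Each of these 10 had an adjusted p of 0.844. The I/R fold of Knl1 was 0.65 with 4 against 4 libraries in place of 1.32, so its difference was smaller there. Among cell cycle members, Cdk1 differed by 1.73 (SE 0.69) and Kif11 by 1.67 (SE 0.58) without passing, from the authors' deposited tables.

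Across genes, the fold changes in SHAM and I/R were positively related. Over 15521 genes Pearson's r was 0.30 and Spearman's rho 0.36, and 63.7% of genes had the same sign. Of the 601 genes called in I/R other than Zeb2os, 518 (86.2%) had the same sign in SHAM, against 63.0% of the genes adjusted and not called. The SHAM and I/R libraries are separate, so these shares do not come from common controls. Genes that move together are not separate checks, and whether the tissue sampled differed alike in both comparisons was not tested.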

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

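The test of the difference between I/R and SHAM was chosen after the form of the tables was known, and the tests of an effect shared with SHAM, of fewer fibroblasts and of a single I/R control library were chosen after related values had been seen. Each result here stands out because its genes stood apart from the other genes in a list test of the difference between I/R and SHAM. That test does not measure the spread between samples.

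The median difference of the log2 fold change, I/R minus SHAM, was 0.28 for oxidative phosphorylation genes, which were higher in both surgeries. Their list test of the difference still passed with 4 against 4 libraries in I/R (cameraPR adjusted p = 0.0116). The I/R median of these genes was then 0.33 in place of 0.46, against 0.18 in SHAM. The size of their difference was therefore smaller there and depends on the I/R control libraries used. Interferon-stimulated genes differed by 0.24, with medians of −0.20 in SHAM and 0.12 in I/R. TGF-beta genes differed by −0.44. Atrial markers differed by −0.53, a call that ended with a preset correlation of 0.05 (adjusted p = 0.055).

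The genes called in I/R followed transcript GC content, and most of the calls ended when that trend was removed. Of the 583 calls with a GC value 1.03% remained. Leaving out Zeb2os, the median size of their log2 fold change went from 0.85 to 0.57. Standard errors were left as deposited (median 0.26), so only the folds could change. Some calls ended with little change of the fold, such as Gfpt2, at −1.18 before and −1.15 after. Of 582 of these calls, which leave out Zeb2os, 84.9% had a GC-adjusted fold of the same sign in the separate SHAM libraries, against 66.5% of the genes not called. A GC-related difference between the I/R libraries may therefore set much of the count of calls, and a Zeb2os effect on part of these genes that SHAM hearts share may also be present. Neither was excluded, and a real effect on genes of low GC content stays open. Genes that move together are not separate checks, so these shares cannot tell a Zeb2os effect from tissue that differed alike in both comparisons.

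Matrix genes (median difference −0.53, a call that ended at adjusted p = 0.055 with a preset correlation of 0.05), fibroblast markers (−0.44) and mural markers (−0.49) were lower with Zeb2os in I/R and less so in SHAM. The GC trend as the whole cause is argued against, since the highest median among the matrix, fibroblast, myofibroblast and mural lists in I/R after its removal was −0.47 and all 4 list tests still passed. A Spearman correlation of fold change with GC content of −0.13 was left in I/R, so a part played by GC content stays open. Fewer fibroblasts in the sampled tissue may account for part, but the test run could not decide it. After the removal 93.8% of the fibroblast markers (n = 16) were below 0. The same share was below 0 before it, so this is not separate evidence. The chi-square test of Cochran's Q of their folds gave 22.6 with 15 degrees of freedom (p = 0.0927), against 26.2 (p = 0.0359) before the removal. A p above 0.05 in that test does not show that the markers fell alike. Of those 16 markers 3 are in other lists as well. The authors' deposited table gives −0.89 (SE 0.55) for Col3a1, −0.49 (SE 0.18) for Gsn, −0.04 (SE 0.26) for Dcn and 0.01 (SE 0.31) for Lum, which are abundant. Lower expression within fibroblasts stays open, as does a difference in the tissue dissected, since the atrial list was lower in I/R as well (median −0.47, adjusted p = 0.0217, 0.00258 with 4 against 4, and 0.0702 with a preset correlation of 0.05) although the labels' protocols name the apex, which lies away from the atria. Of the 15 mural members 3 are in other lists as well, among them Acta2, which is also a myofibroblast marker. Whether the fall of the mural list follows from fibroblast numbers was therefore not decided.

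Cell cycle genes differed by 0.80, with a median of −0.49 in SHAM and 0.35 in I/R. The GC trend as the whole cause is argued against, since the median difference after its removal was 0.79. Spearman correlations of fold change with GC content of −0.13 in I/R and −0.05 in SHAM were left. With 4 against 4 libraries in I/R the median difference was 0.58, which is 72.4% of the value with 4 against 3 and still passed (adjusted p = 2.01e-09), while the I/R median alone was 0.21 and no longer passed (adjusted p = 0.0717). The choice of I/R control libraries therefore moved the size of the difference. How much of the 0.58 that was left comes from that choice, from spread between samples or from an effect of surgery on the response to Zeb2os cannot be told apart. Values per library were not analysed here.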

How the results depend on the processing

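The adjusted p threshold of 0.10 for the counts in SHAM and I/R and the correlation over genes past an unadjusted p were planned, and the other alternatives here were chosen after seeing the data. The count of genes past the threshold in I/R, 602, became 2090 at an adjusted p under 0.10, 284 when adjusted over genes with a mean of at least 10, and 12 when adjusted over every gene with a p, where more genes of low counts are tested. It became 9 with GC-adjusted fold changes and 1 in the authors' deposited table of 4 against 4 libraries, both unfiltered and filtered at 10. There the median size of the called folds went from 0.85 to 0.51 and their median standard error from 0.26 to 0.32, and why the folds shrank was not tested. All 602 genes kept their sign with 4 against 4, which shares libraries with 4 against 3, and 210 of them had an unadjusted p under 0.05 there. Adjusted over genes with a mean of at least 50 or 200 the count was 576 or 656, and the authors' deposited table filtered at 10 has 498, of which 490 are among the 602. The SHAM count of 1 and the difference count of 0 stayed the same under each alternative run, including an adjusted p under 0.10 and the GC adjustment. The correlation of SHAM and I/R fold changes, 0.30, was 0.43 over genes past an unadjusted p of 0.05 in either comparison and 0.40 over genes with a mean of at least 50, and the cause was not tested. Zeb2os stayed past the threshold throughout. Of the 35 other genes past the threshold that the I/R part of the naming rule took, 35 ended with 4 against 4, 34 after GC adjustment, which kept Lmod1, and 4 with the filtered table of 4 against 3 (Cilp2, Dld, Esco2 and Tgfb3). No list or gene past its threshold turned its sign. A preset correlation of 0.05 ended 9 of the 35 list calls, the GC adjustment 1 and ranks none. A mean of at least 50 kept 33 and ended 1, the sarcomere list in I/R (adjusted p = 0.052). The table of 4 against 4, which bears on I/R and the difference only, kept 20 and ended 1, the cell cycle list in I/R (adjusted p = 0.0717). Calls were gained too, since 15 lists passed in I/R after GC adjustment, of which 12 had passed before, and 14 with 4 against 4 or by ranks. The planned count models, other scalings, leave-out fits, other splits of the samples, comparisons of I/R with SHAM, list tests with an estimated correlation and a fit of all groups need values per library and were not run. No paired analysis was possible because the columns carry no replicates and the labels tie no samples of different groups together. Depth per library is unknown, and the authors' adjusted p in I/R is given only for genes with a mean of at least 68.0 normalized counts.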

Other observations

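The gene families here were chosen after the data were seen. In I/R hearts subunit genes of respiratory complex I had a median log2 fold change of 0.45 with 45 of 47 above 0 (cameraPR adjusted p = 6.83e-12), and 6 rose, among them Ndufa5 by 1.02 (SE 0.30) in the authors' deposited table. Mitochondrial ribosome genes had a median of 0.29 with 72 of 78 above 0 (adjusted p = 4.67e-11), and 8 rose. Proteasome genes (0.29, adjusted p = 1.18e-07) and cytosolic ribosome genes (0.17, adjusted p = 7.27e-06) were higher too. In SHAM the medians of these 4 families were 0.13, 0.14, 0.11 and 0.07, and each passed there, although with a preset correlation of 0.05 the cytosolic ribosome call in SHAM ended (adjusted p = 0.132). Zinc finger genes had a median of 0.18 in I/R (adjusted p = 1.42e-04), and 37 of 363 rose while 9 fell. That call ended with a preset correlation of 0.05 (adjusted p = 0.0586). With 4 against 4 libraries the zinc finger median was 0.11 (adjusted p = 0.0316, or 0.29 with a preset correlation of 0.05), and 0 members passed. Their median was 0.05 with an adjusted p of 0.238 once the GC trend was removed, and 0.01 in SHAM (adjusted p = 0.957).

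Collagen genes had a median of −0.78 in I/R with 38 of 42 below 0 (adjusted p = 1.18e-07) and of −0.33 in SHAM with 39 of 42 below 0 (adjusted p = 1.08e-05). Notch pathway genes had a median of −0.43 in I/R (adjusted p = 6.06e-04), and 3 of 13 fell. In the authors' deposited table these were Notch1 by 0.72 (SE 0.23), Notch3 by 0.74 (SE 0.22) and the target gene Heyl by 0.81 (SE 0.26). Semaphorin and ephrin genes had a median of −0.42 with 46 of 53 below 0 (adjusted p = 5.09e-07), and 2 fell. Once the GC trend was removed the Notch median was −0.21 (adjusted p = 0.0237) and the semaphorin and ephrin median −0.26 (adjusted p = 2.01e-05), and with 4 against 4 libraries they were −0.29 (adjusted p = 0.0223) and −0.24 (adjusted p = 2.65e-05). The Notch call with 4 against 4 ended with a preset correlation of 0.05 (adjusted p = 0.0579) and after GC adjustment (0.174). No member of any family here passed over all genes with 4 against 4. The Notch (median −0.13, adjusted p = 0.318) and semaphorin and ephrin (−0.09, adjusted p = 0.17) families did not pass in SHAM.

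Among the terms in the authors' deposited tables for genes higher in I/R, the lead process was regulation of transcription by RNA polymerase II with 48 genes, followed by cell cycle with 27 and translation with 18. For genes lower in I/R the lead processes in the authors' deposited tables were positive and negative regulation of transcription by RNA polymerase II with 36 and 32 genes and multicellular organism development with 33. Further down the authors' deposited tables list chondrocyte differentiation with 9 genes at 17.9-fold, epithelial to mesenchymal transition with 8 at 22.2-fold and the Notch signaling pathway with 9 at 9.5-fold. A Benjamini value under 0.05 was given for 7 of 69 process terms of higher genes and 35 of 234 of lower genes in the authors' deposited tables. The background of the enrichment is not stated, and the terms were not tested again here. They concern genes changed in I/R, where 1 of 602 calls stayed with 4 against 4 libraries and 6 of 583 after GC adjustment.

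Some genes with a mean of at least 10 normalized counts have a fold change without a p-value. There were 23 of 15671 such genes in I/R, of which 10 were lower and 13 higher, and 6 of 15707 in SHAM. They held 2 of the 11 atrial markers in I/R, singled out after their values were seen. These were Sln (sarcolipin) at −3.39 (SE 2.74) and Myl7 (atrial myosin light chain) at −3.02 (SE 2.08) in the authors' deposited table. Mybphl stood at −3.20 (SE 1.81) in the authors' deposited table, and Rn45s, Lars2, Arg1, Marco and Trem1 were also without a p. Why these genes have no p is not given in the sources used here. Without values per library it cannot be told whether single libraries set their folds. The atrial median in I/R covered 9 members without Sln and Myl7, while the list test in I/R held all 11. The test of the difference left both out.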
